A study of Mus with 50 samples.

How the data were processed

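Liver total RNA of 50 female mice was profiled on 1 Affymetrix whole-transcript array each. Per the labels' protocols, 100 ng of total RNA was amplified and biotin-labelled with the WT Plus kit. The labels name the tissue as liver, whereas the extraction protocol speaks of purified cells; the values are taken here as liver. The deposited values are log2 signals, which the authors made with RMA in Affymetrix Expression Console 1.4.1, per the submitters' processing notes. RMA corrects background, normalises arrays by quantiles and summarises probes, so differences in overall RNA amount between livers are removed, and values of different probes cannot be set against each other as amounts. All value columns matched a sample. The table holds values from 1.45 to 13.54.

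Of 41345 probe sets, 23521 carried 1 gene symbol, 1814 carried several and 16010 carried none in the platform annotation used; no gene was named from a probe set with several. Of several probe sets of a gene the one with the highest median was used, which left 22180 genes. Gene order along chromosomes came from a RefSeq table of assembly GRCm38.p6 and was used for neighbours only.

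The labels put all mice in 1 group, so spread and covariation over mice were analysed. The mice are separate animals by their numbers. Of 402 genes in 30 fixed lists, 353 were measured; 17 of the others sit only on shared probe sets, and the remainder were not analysed here. For each list the mean pairwise Pearson r was tested by shuffling each member over mice (10000 permutations, one-sided, Benjamini-Hochberg over lists) and set against 10000 random lists of the same size and like level. The SD was treated in the same way without a p. A list score is the mean of its members' values standardised over mice. A member followed its list when its r with the score of the other members was positive at an adjusted p under 0.05 over all 353 members. Relations between scores were tested with Pearson's r and Spearman's rho (two-sided, 100000 permutations), adjusted over the 57 relations of the oxidative lists and over all 435 pairs, with r again without the 2 mice farthest from the median of the first score. Where a score fell into separate clusters, no pooled r was given. Relations of the neutrophil score were then computed within its clusters, a test chosen after the data were seen, with 10000 permutations in the larger one, adjusted over the other lists.

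Genes were fitted on the animal number with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend) and compared with 100 random orders. Separate clusters were sought with a normal mixture of 2 components, requiring a BIC gain above 10, a distance of at least 4 SD and 0.5 log2, and 5 mice in each. Pairs of neighbouring genes whose symbols share 3 first letters were left out. Mice stand apart when their median correlation with the others lies more than 3 interquartile ranges below the lower quartile. Stretches of animal numbers were sought after the data were seen, by binary segmentation of ranked values with at least 8 mice per stretch; a step was kept when its share of the variance exceeded that of 100 random orders. Relations within stretches were permuted within them. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

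The lists, the tests named so far other than those on stretches and within score clusters, and the rule for named genes were fixed before the data were examined. The rule allowed naming of the up to 4 members closest to their list and the most variable member, all members of the 2 oxidative lists, the 15 genes with the largest SD, the 10 clearest clustered genes, the 10 genes most related to the animal number, and Erbb2 and Nnt. Chosen after their values were seen were Cd68, Csn3, Csn1s2a and Wap in single mice, 2610507I01Rik, Gm7969, Snord99, Olfr1034 and Scarna6 among clustered genes, and the genes of 4 lists added later (pancreatic acinar, adipocyte, epithelial and erythroid precursor).

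The steps were tested on simulated data. For the fit on the animal number over 11090 genes, 3.5% of 200 changed genes were recovered at a slope of 0.1 log2 per 100 numbers, 62.5% at 0.2 and 94% at 0.4, and unchanged genes made up 12.5%, 4.58% and 6% of the calls. Among simulated data without any relation, 8 of 100 lists and 8 of 100 correlations had an unadjusted permutation p under 0.05. Alternatives covered the choice of probe sets, level filters, array centring, ranks, residuals on the animal number, clock, first array component and blood and immune scores, the score definition, and the mice that stand apart.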

Results

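Gene expression was measured in the livers of 50 female mice, with 1 array per mouse. The mice came from a backcross between the C57 and FVB strains and carried MMTV-Neu, a transgene in which a mouse mammary tumour virus promoter drives the Neu proto-oncogene in the mammary gland. Per the series design, the livers were chosen from mice at the extremes of an ageing grade, and the title ties that grade to oxidative stress and to breast cancer. The labels do not say which mouse lay at which extreme. All 50 livers therefore formed 1 group, no comparison between ageing grades was made, and each value below is a spread or a covariation over mice that pools both extremes. Each mouse is named by the animal number in its title. Values are log2 signals, and array medians lay between 3.27 and 3.34. The number of arrays limits the precision. Of 22180 named genes, the 11090 at or above the median level of 3.61 were used where a level filter is stated.

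Most genes varied little between livers, and a few varied widely. The SD over mice had a median of 0.28 over the 11090 genes, with 5% of genes below 0.17 and 5% above 0.67. Serpina1d, which encodes an alpha-1 antitrypsin of the liver, had the largest SD at 3.07, and its signal ran from 3.80 to 12.15. Cyp4a14, a fatty acid hydroxylase induced through PPAR-alpha, followed with an SD of 2.24 and a range of 8.24. The acute phase gene Saa2 had an SD of 1.99, with 80% of mice between 6.13 and 10.99. Hamp2, a relative of the iron hormone hepcidin, had an SD of 1.96. The steroid and sulphate enzymes Cyp17a1, Sult2a1, Sult2a3, Sult2a6 and Sult1e1 had SDs of 1.89, 1.79, 1.77, 1.65 and 1.61. The pseudogene Serpina4-ps1 and Rabggtb, a subunit of a prenyl transferase for Rab proteins, had SDs of 1.89 and 1.52. The spread of Rabggtb went with the animal number, and its cause was not tested. Its values ran from 7.78 to 10.14 in animals 7 to 128 and from 4.08 to 7.95 in animals 137 to 235. In animals 253 to 301 they ran from 4.58 to 8.87. Ctrb1, a digestive protease of the pancreas, had an SD of 1.70 around a median of 4.34 and reached 12.30 in animal 96.

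**Figure D1:**
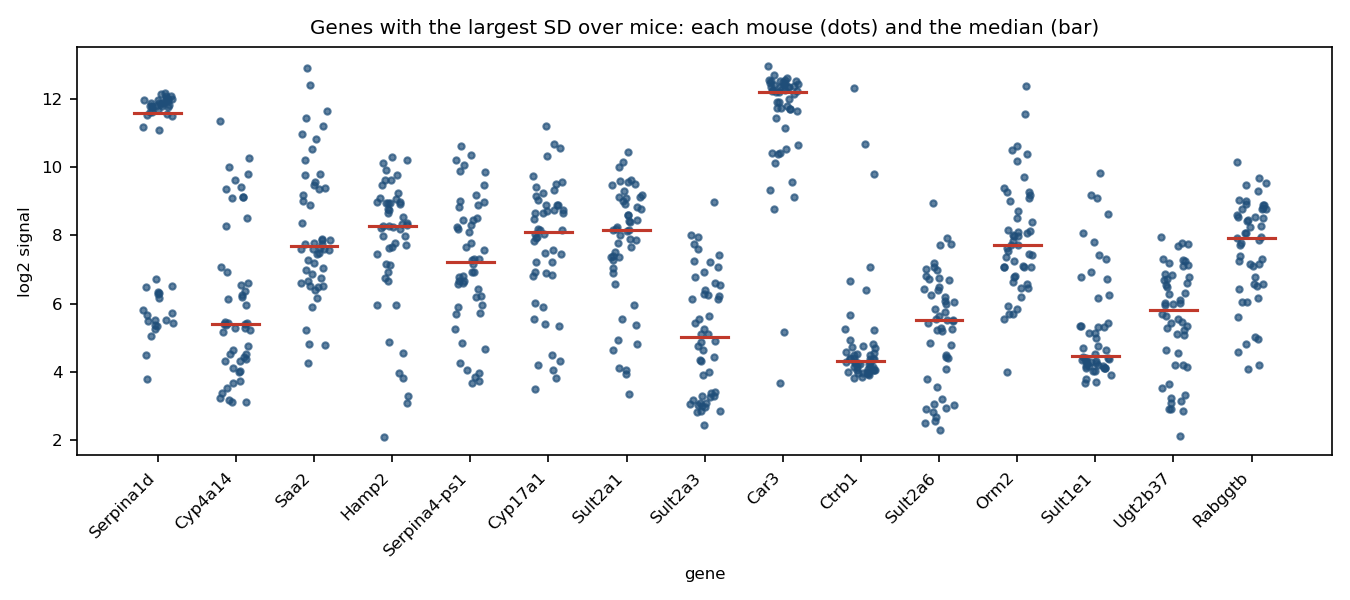
Log2 signal (vertical axis) of the 15 genes with the largest SD over mice (horizontal axis, in order of SD); each dot is 1 of 50 mice and the bar is the median. Serpina1d falls into a lower set of 20 mice and an upper set of 30, and Ctrb1 lies near 4.34 in most mice with a few far above.

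Genes of cholesterol synthesis, lipogenesis and other metabolic lists covaried within their lists from mouse to mouse. All 13 measured cholesterol synthesis genes followed the rest of their list, with a mean pairwise r of 0.822. Fdps, a prenyl transferase of that pathway, ran from 5.55 to 10.02. All 13 measured lipogenesis genes did so too, with a mean r of 0.696; Fasn, the fatty acid synthase, had 80% of mice between 9.06 and 10.71, and Pnpla3 had the largest SD of the list at 1.48. Animals 64, 84, 87 and 235, the 4 that stand apart, had cholesterol synthesis scores of −2.92, −3.13, −3.21 and −1.29. Their lipogenesis scores were −2.58, −2.20, −1.67 and −1.99. By Spearman's rho the mean was lower, at 0.648 for cholesterol synthesis and 0.628 for lipogenesis. Without these 4 mice all 13 genes of either list still followed. Among PPAR-alpha targets, 12 of 13 followed their list, with a mean r of 0.352. The counts were 8 of 8 for gluconeogenesis, with a mean r of 0.495, and 9 of 10 for bile acid synthesis and transport, with a mean r of 0.484. Without the 4 mice that stand apart, described below, 5 gluconeogenesis and 7 bile acid genes did, with mean r falling to 0.216 and 0.215. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had an SD of 1.22.

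Xenobiotic and sex-biased enzymes were also variable. Of 11 xenobiotic metabolism genes 9 followed their list, with a mean r of 0.352, and Cyp1a2 ran from 4.50 to 10.62. Of 10 female-biased liver genes 8 did, with a mean r of 0.403, and their median SD of 1.18 was the highest of any list. Without the 4 mice 8 xenobiotic and 6 female-biased genes followed, with mean r of 0.231 and 0.263. On residuals of the first array component the mean r was 0.111 for the xenobiotic, 0.158 for the female-biased and 0.028 for the bile acid list. Without the 4 mice the female-biased median SD was 0.83, and that of mammary epithelium, where animal 161 scored 4.82 and the next mouse 0.56, was 0.92. The median ranges that hold 80% of all 50 mice were 2.35 for the female-biased and 0.40 for the mammary epithelium list. The 21 oxidative phosphorylation genes showed the opposite combination. They moved together, with 19 of 21 following their list and the mean r above those of all random lists, yet their median SD of 0.24 lay at percentile 0.77 of random lists of like level.

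Heat shock, interferon response and acute phase genes each covaried within their list. All 10 heat shock genes followed their list, with a mean r of 0.511, and Hspa1b, an inducible chaperone, ran from 3.75 to 9.06. All 14 interferon response genes did so, with a mean r of 0.561, and Usp18 ran from 3.23 to 8.68. In the acute phase list 18 of 19 genes did so, with a mean r of 0.522. In the endoplasmic reticulum stress list 7 of 13 followed and 2 ran against it, with a mean r of 0.117, led by the chaperone genes Creld2, Hspa5, Sdf2l1 and Hsp90b1. That list lost its call when each array was centred on its median and after removal of 2 clock components. The lists not called were the primary antioxidant enzymes, p53 and senescence, iron handling and clock lists, whose mean r lay between 0.0451 and 0.0517. In the p53 and senescence list 2 of 11 genes followed the others. These were Cdkn1a, a cell cycle inhibitor, with 80% of mice between 6.45 and 8.83, and Btg2, with an SD of 1.13. Adjusted over the list alone, the counts of followers of the metabolic, stress and inflammatory lists named above were the same, except 13 for PPAR-alpha targets.

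In all, 26 of 30 lists covaried over mice. A list was called when its mean r passed an adjusted p of 0.05 in a one-sided permutation test and lay above percentile 95 of 10000 random lists of like level. The permutation p was 0.0001, the smallest that 10000 permutations can give, for 25 of the 26 (adjusted p = 0.00012), and the male-biased list had an adjusted p of 0.00156 by permutation. The male-biased call was lost with centred arrays, on residuals of the first array component and of the blood and immune scores, and without the 4 or the 15 mice described below. The bile acid list lost its call on residuals of the first component and the mammary epithelium list without the 15 mice, and the iron list gained one with Spearman's rho. The between-mouse spread lay above percentile 95 for 26 of 30 lists. The exceptions were the antioxidant enzyme, endoplasmic reticulum stress, oxidative phosphorylation and hepatocyte lists. By the range that holds 80% of mice, the mammary epithelium and cholangiocyte lists lay at percentiles 69.3 and 62.3 and were not wide, and endoplasmic reticulum stress, at percentile 97.6, was.

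Of the 2 oxidative stress lists, which the title of the series brings forward, the NRF2 targets covaried weakly and the primary antioxidant enzymes were not called. Among NRF2 targets, the inducible detoxification genes, 8 of 15 measured members followed the rest of the list over all genes tested, and 7 when adjusted over the list alone. They were Ugdh, Txnrd1, Gsr, Srxn1, Gstm1, Gstm3, Nqo1 and Gclc. Gstm3, a glutathione transferase, varied most, with an SD of 0.94 and a range from 4.94 to 9.55. Ugdh, which makes UDP-glucuronate, had 80% of mice between 8.13 and 9.29. The 7 members that did not pass included Gclm, with 80% of mice between 9.58 and 10.00, and Hmox1, the haem oxygenase, with an SD of 0.79. The mean r of the list was 0.115, at percentile 97.5 of random lists. Its call was lost with the mean of all probes of a gene, at percentile 93.6, and with arrays centred on their medians, at percentile 88.8.

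Primary antioxidant enzymes did not covary beyond random lists of like level. Their mean r of 0.050 lay at percentile 72.4. Sod1, Txn2, Msra and Cat followed the others, Gpx3 ran against them, and 9 of 14 did not pass; adjusted over the list alone, 4 again followed and Gpx3 did not pass. Sod1, the cytosolic superoxide dismutase, had a median of 11.39 and an SD of 0.24. Cat, the catalase, had a median of 12.45 and an SD of 0.33. Gpx3 had an SD of 1.12 and reached 10.23 against a median of 4.25.

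Livers with higher antioxidant enzyme scores, from a list not called as coherent, had higher oxidative phosphorylation scores. Which enzymes of the list carry this relation was not tested. Over 50 mice r was 0.731 (permutation p = 1e-05, the smallest possible, adjusted p = 0.00057) and rho was 0.697 (permutation p = 1e-05). Without the 2 mice farthest on the antioxidant score r was 0.698. Within the 4 stretches of animal numbers described below r was 0.803, 0.830, 0.893 and 0.525. Without the 15 mice that stand apart or lie far out on a cell type list, described below, r was 0.587 (adjusted p = 0.0057 by permutation). Cell type markers moved with the antioxidant score. Its r with the stellate and fibroblast score was −0.503 (permutation p = 0.00014, adjusted p = 0.00199), rho was −0.488 (permutation p = 0.0003) and r without 2 mice was −0.423. Within stretches that r was −0.617, −0.729, −0.589 and −0.340, and without the 4 mice that stand apart its adjusted p was 0.0654 by permutation, with r = −0.337. With the hepatocyte score r was 0.510 (permutation p = 0.00029, adjusted p = 0.00331), rho was 0.502 (permutation p = 0.0002) and r without 2 mice was 0.454, and within stretches r was 0.604, 0.150, 0.838 and 0.049. Without the 15 mice that r was 0.458 (adjusted p = 0.0674 by permutation), and on residuals of the first array component the relation was lost, as given below. Relations with the macrophage and cholangiocyte scores passed over all mice, with r = −0.350 and −0.363 (adjusted p = 0.0358 and 0.0316 by permutation). Their rho was −0.130 and −0.121. Without 2 mice r was −0.121 and −0.264 (unadjusted permutation p = 0.412 and 0.0722). Within stretches both passed, with r = −0.464 and −0.406 (adjusted p = 0.013 and 0.0377 by permutation). Without the 4 mice that stand apart r was −0.061 and −0.540 (adjusted p = 0.795 and 0.0057 by permutation). The oxidative phosphorylation score passed with the stellate, macrophage and hepatocyte scores too (adjusted p = 0.0006, 0.000466 and 0.0442 by permutation), lower, lower and higher. The antioxidant score also rose with the xenobiotic score, with r = 0.571 (permutation p = 6e-05, adjusted p = 0.00114), rho = 0.513 (permutation p = 0.0001) and r = 0.515 without 2 mice. Within stretches that r was 0.738, 0.253, 0.768 and 0.610. Without the 15 mice it was 0.378 (adjusted p = 0.0947 by permutation).

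NRF2 target scores rose with oxidative phosphorylation scores as well. Here r was 0.469 (permutation p = 0.0007, adjusted p = 0.00443), rho was 0.470 (permutation p = 0.00061) and r without 2 mice was 0.381. Within stretches r was −0.134, 0.398, 0.711 and 0.583, so it was not positive among the 8 mice of the first stretch, and without the 15 mice it was 0.464 (adjusted p = 0.0674 by permutation). NRF2 target and antioxidant enzyme scores were related with r = 0.358 (permutation p = 0.00997, adjusted p = 0.0316), rho = 0.361 (permutation p = 0.0105) and r = 0.308 without 2 mice. Within stretches that r was 0.107, 0.204, 0.648 and 0.482, and without the 4 mice that stand apart it was 0.323 (adjusted p = 0.0753 by permutation). Without the 15 mice it was 0.429 (adjusted p = 0.0726 by permutation).

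In this family of 57 relations 22 passed an adjusted p of 0.05. The 2 with the neutrophil list carry no pooled r, because that score fell into separate clusters of 8 and 42 mice. Of the remaining 20, 15 were positive and 5 negative, and for 5 the permutation p without the 2 mice farthest on the oxidative score, not adjusted, was above 0.05. After removal of the 15 mice 1 of the 20 passed, that of antioxidant enzymes with oxidative phosphorylation. The antioxidant and cell cycle scores had r = −0.411 (permutation p = 0.00401, adjusted p = 0.0152) and rho = −0.198 (permutation p = 0.169). Without 2 mice r was −0.323, within stretches it was −0.668, −0.533, −0.665 and −0.043, and without the 15 mice it was 0.189.

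**Figure D2:**
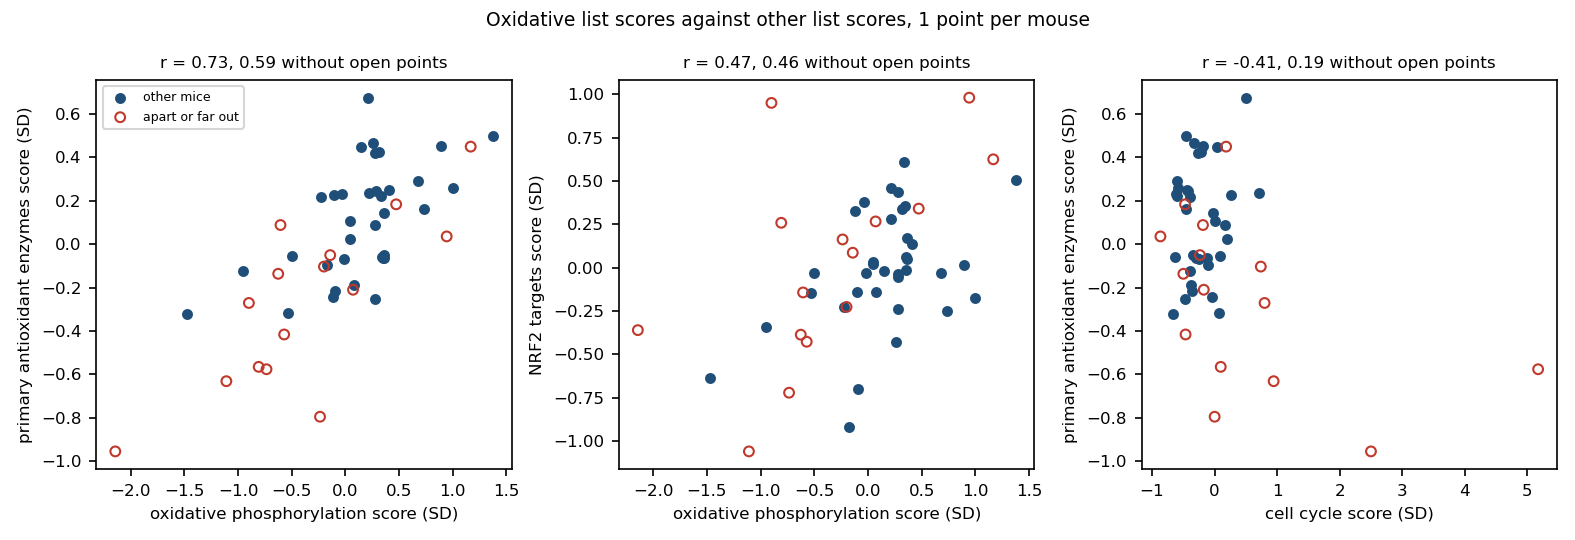
List scores of 50 mice (mean of values standardised over mice, in SD): antioxidant enzymes against oxidative phosphorylation, NRF2 targets against oxidative phosphorylation, and antioxidant enzymes against cell cycle. Open points are the 15 mice that stand apart or lie far out on a cell type list; without them r goes from 0.731 to 0.587, from 0.469 to 0.464 and from −0.411 to 0.189.

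Bile acid, xenobiotic and female-biased scores were related in each pair. Each of these scores had a few mice far below the rest, at distances of 6.57, 5.23 and 5.43 SD, with 47, 46 and 46 mice in the upper set. The hepatocyte and growth hormone scores were alike, at 7.30 and 5.22 SD with 48 mice in each upper set. They carry a pooled r only because the rule for clusters asks for 5 mice in each. Bile acid and xenobiotic scores had r = 0.899 (permutation p = 1e-05, adjusted p = 0.000242) and rho = 0.724 (permutation p = 1e-05). Without 2 mice r was 0.783, within stretches it was 0.948, 0.859, 0.924 and 0.810, and without the 15 mice it was 0.730. Bile acid and female-biased scores had r = 0.876 (permutation p = 1e-05, adjusted p = 0.000242), rho = 0.643 (permutation p = 1e-05), r = 0.735 without 2 mice and r = 0.736 without the 15 mice. Its r within stretches was 0.971, 0.887, 0.835 and 0.714. Xenobiotic and female-biased scores had r = 0.863 (permutation p = 1e-05, adjusted p = 0.000242), rho = 0.620 (permutation p = 1e-05), r = 0.730 without 2 mice and r = 0.729 without the 15 mice, and within stretches r was 0.909, 0.866, 0.894 and 0.661. Among the 42 mice of the lower neutrophil cluster, the neutrophil score ran against the xenobiotic score, with r = −0.570 (permutation p = 0.0001, the smallest possible, adjusted p = 0.00145), rho = −0.436 (permutation p = 0.0047), r = −0.501 without 2 mice and r of −0.465, −0.730, −0.616 and −0.747 within stretches. It ran against the female-biased score too, with r = −0.548 (permutation p = 0.0001, adjusted p = 0.00145), rho = −0.484 (permutation p = 0.0008), r = −0.519 without 2 mice and r of −0.390, −0.632, −0.601 and −0.485 within stretches. In the 8 mice of the upper cluster these r were 0.465 and 0.485. Of the 14 neutrophil genes 3 lay at or above the median level, so the score rests in part on values near the floor. The 42 mice include animals 84, 87 and 235, which stand apart, with xenobiotic scores of −1.39, −0.39 and −2.01. No r without them is given for the 42 mice. The xenobiotic and female-biased lists were not the only ones related to the neutrophil score in the 42 mice. Its largest r was with the endothelial score, at 0.614 (permutation p = 0.0002, adjusted p = 0.00193), with rho = 0.595. Within stretches that r was 0.848, 0.660, 0.528 and 0.741, and in the 8 mice it was 0.232. The macrophage and lipogenesis scores were among others that passed, with r = 0.380 and −0.528 (adjusted p = 0.0308 and 0.00507 by permutation). For the bile acid score in the 42 mice r was −0.497 (permutation p = 0.0009, adjusted p = 0.00522), rho −0.374 (permutation p = 0.0146) and r without 2 mice −0.435; within stretches r was 0.053, −0.762, −0.572 and −0.317, and in the 8 mice it was 0.335. The growth hormone and IGF axis followed the hepatocyte score, with r = 0.888 (permutation p = 1e-05, adjusted p = 0.000242), rho = 0.695 (permutation p = 1e-05), r = 0.752 without 2 mice and r = 0.669 without the 15 mice. Within stretches that r was 0.945, 0.907, 0.890 and 0.732. Macrophage and endothelial scores had r = 0.547 (permutation p = 0.00021, adjusted p = 0.00208), rho = 0.592 (permutation p = 1e-05), r = 0.477 without 2 mice and r = 0.718 without the 15 mice. Within stretches that r was 0.068, 0.662, 0.459 and 0.820. The p53 and senescence score, from a list not called as coherent, fell as the lipogenesis score rose, with r = −0.610 (permutation p = 1e-05, adjusted p = 0.000242), rho = −0.559 (permutation p = 4e-05), r = −0.539 without 2 mice and r = −0.526 without the 15 mice. Within stretches that r was −0.838, −0.862, −0.254 and −0.678. A p of 1e-05 is the smallest that these permutations can give.

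Of 435 pairs of lists 140 passed an adjusted p of 0.05, of which 11 with the neutrophil list carry no pooled r. The other 129 comprised 83 positive and 46 negative pairs. Of these, 55 did not pass an unadjusted p of 0.05 without the 2 mice farthest on the first score, 111 passed within stretches, 47 passed without the 4 mice that stand apart, and 25 passed without the 15 mice. The 6 pairs with all 50 mice named above were among 22 that passed in each of these 4 checks.

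Cell type markers separated single livers from the rest. Animal 64 had an erythroid score of 5.72, a cell cycle score of 5.17 and a hepatocyte score of −4.06, where scores are means of values in SD over mice. Its Slc4a1, the red cell anion exchanger, was 10.92 against a median of 4.33, and its Mki67, a proliferation marker, was 11.13 against 5.43. Animal 235 had a macrophage score of 3.74, a cell cycle score of 2.50 and a hepatocyte score of −1.94, with Cd68 at 10.85 against a median of 7.17. The T cell score of animal 87 was 5.31, with Cd3e at 8.25 against 4.23. Animal 10 had a B cell score of 4.29, with Ms4a1, which encodes CD20, at 8.45 against 3.51. Animal 96 had the highest cholangiocyte score, 4.07, and animal 161 the next, 2.99. In animal 161 the neutrophil score of 2.58 was the highest and the mammary epithelium score was 4.82, and the milk protein gene Csn2 was 12.05 against a median of 2.41. Erbb2, the mouse counterpart of the Neu transgene, was 9.65 in animal 161 and 5.36 in animal 84 against a median of 3.49. Nnt, partly deleted in a C57BL/6 substrain, had a median of 7.81 and lay between 6.17 and 8.28.

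The 4 mice that stood apart were animals 64, 235, 84 and 87, with median correlations to the other livers from 0.794 to 0.932 against a median of 0.972 over mice. Together with the mice far out on a cell type or pancreatic acinar list, they make up the 15 mice left out above, a choice made after the data were seen. Animals 24, 142 and 301 were left out only for acinar scores of 0.46, 0.60 and 0.59. The quartiles of that score lay close together, at −0.32 and −0.22, and animal 96 scored 5.36.

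**Figure D3:**
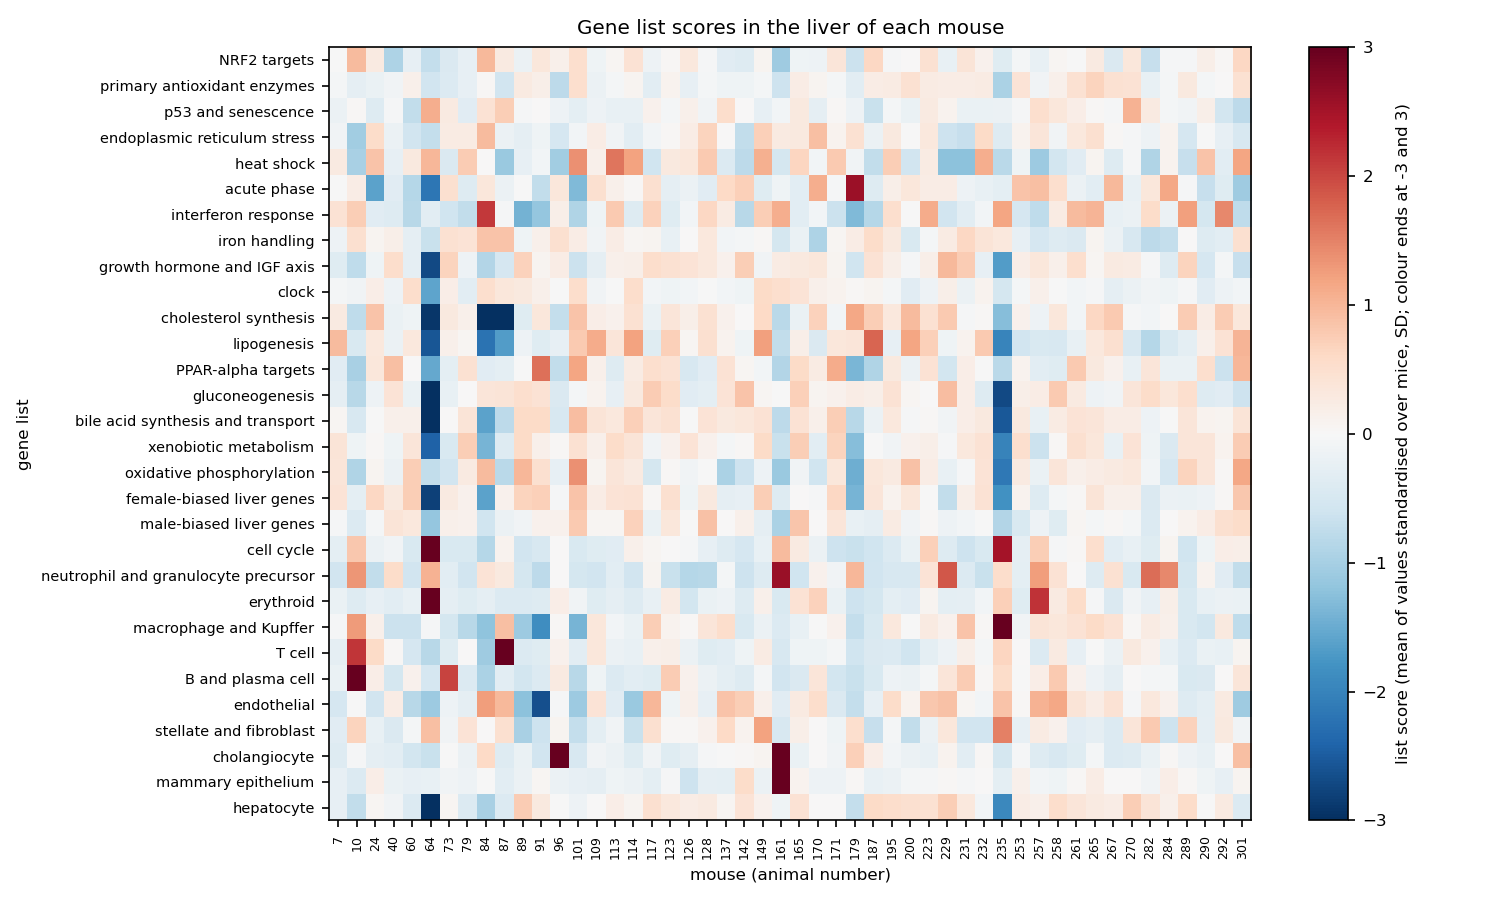
Scores of the 30 gene lists (rows) in the 50 mice (columns, by animal number), as means of values standardised over mice, in SD; the colour scale ends at −3 and 3. Animals 64 and 235 have high cell cycle and low hepatocyte scores, animal 87 a high T cell score, animal 10 a high B cell score and animal 161 a high mammary epithelium score.

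Gene levels were related to the animal number, the only value in the labels that differs between mice, whose meaning the labels do not give. With limma 1031 of 11090 genes passed an adjusted p of 0.05, 365 higher and 666 lower at higher numbers; with arrays centred on their medians 589 of 1055 were higher. Rnf10, a ubiquitin ligase gene, fell by 0.42 log2 per 100 numbers (SE 0.041, limma adjusted p = 3.97e-10). The chromatin genes Phf2 and Kmt2d fell by 0.28 and 0.34 per 100 numbers, and Pcnx3, Fbrs and Atp6v0a2 fell by 0.33, 0.36 and 0.30. Klhl2 rose by 0.25. Ndufc2, a subunit of complex I, Dusp11 and Dennd6a fell by 0.23, 0.28 and 0.23. All 10 kept their direction with centred arrays.

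Sets of neighbouring numbers differed more than in random orders, a comparison that does not separate a step from an even slope. The step before animal 137 took 6.28% of the variance of ranked values, against at most 4.52% in 100 random orders. Within the lower numbers the step before animal 84 took 13.0% against 8.94%, and within the higher numbers that before animal 253 took 10.6% against 8.12%. They divided the mice into 4 stretches of 8, 13, 16 and 13 mice. The stretch means were 7.06, 6.67, 6.72 and 6.25 for Phf2 and 5.72, 5.47, 5.51 and 4.84 for Pcnx3. They were 6.67, 6.30, 6.33 and 5.73 for Kmt2d and 6.54, 6.06, 6.17 and 5.49 for Fbrs. None of these genes fell from the second to the third stretch. Atp6v0a2 had means of 6.99, 6.98, 6.86 and 6.28. Each gene was lowest in the last stretch, from animal 253. For Rnf10 the stretch means were 9.21, 8.92, 8.80 and 8.11, and the slope within stretches was −0.09 (SE 0.11). For Dennd6a, Ndufc2 and Dusp11 it was 0.21 (SE 0.086), 0.08 (SE 0.088) and 0.08 (SE 0.13), opposite in sign to the slope over all mice. With the stretches as a block, limma called 0 genes, and 689 had an unadjusted p under 0.05.

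**Figure D4:**
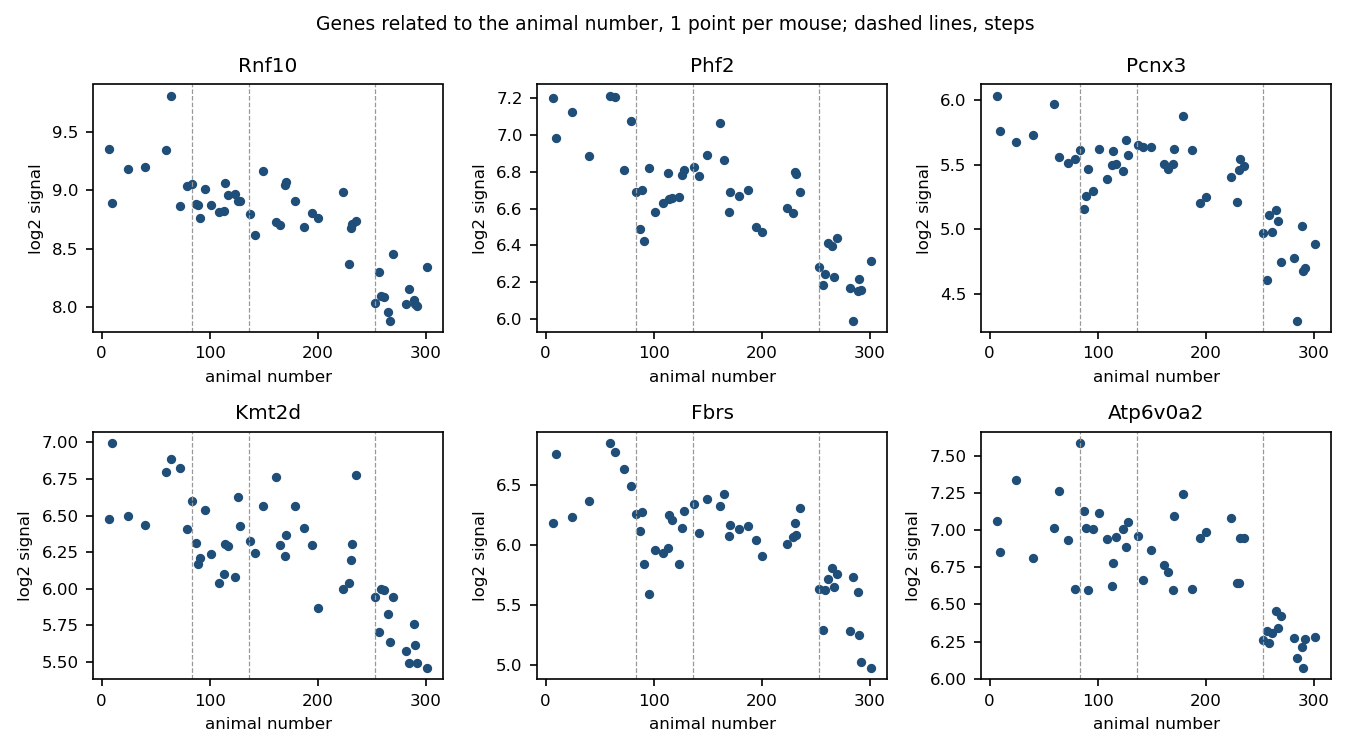
Log2 signal (vertical axes) against animal number (horizontal axes) for the 6 genes with the smallest adjusted p, 1 point per mouse (50 mice); dashed lines mark the steps before animals 84, 137 and 253. All 6 genes are lowest on the right, and Rnf10 averages 8.11 in the last 13 mice.

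Genes close together on a chromosome covaried slightly more than genes on different chromosomes. Pairs 1 to 5 genes apart had a mean r squared of 0.0768, against 0.0704 for pairs on different chromosomes. The excess of 0.0064 was above that of all 100 random reassignments of positions, whose highest was 0.00101. The mean r squared was 0.0726 at 6 to 20 genes, 0.0712 at 21 to 50 and 0.0711 at 51 to 100. At 101 to 200 genes it was 0.0702 and beyond 200 it was 0.0690, both below the value for different chromosomes. These are correlations over mice averaged across gene pairs, which are not independent.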

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

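Alternatives within stretches of animal numbers, with stretches as a block, with blood and immune covariates on the animal number, and without the 15 mice were chosen after the data were seen. Covariation was called for 23 to 27 of 30 lists, and for 24 of 28, 25 of 29 and 20 of 25 where fewer lists were scored. Wide spread was found for 24 to 27 of 30, and for 23 of 28, 25 of 29 and 22 of 25. The neighbour excess stayed between 0.00508 and 0.00897, under all alternatives run. The 22 relations of the oxidative lists became 4 on residuals of the first array component, 7 of 47 on residuals of the blood and immune scores and 1 without the 15 mice. Fewer mice did not account for the last count by themselves, since 100 random sets of 35 mice gave from 4 to 25, with a median of 14; the cause of the others was not tested. The other alternatives gave from 15 to 32. The 140 pairs became 79 with Spearman's rho, 50 on residuals of the first component, 85 without the 4 mice that stand apart, 63 of 300 on residuals of the blood and immune scores, and 50 without the 15 mice, and from 135 to 158 otherwise. The cause was not tested.

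On residuals of the first component, the relation of antioxidant enzymes turned to r = −0.117 with the growth hormone and IGF axis, −0.011 with lipogenesis, −0.043 with gluconeogenesis, −0.040 with female-biased genes, −0.036 with male-biased genes, 0.260 with cell cycle and −0.027 with hepatocyte markers, none of which passed. Without the 15 mice its r with cell cycle was 0.189, and with Spearman's rho that with mammary epithelium, whose r was −0.153, was 0.3999, which passed (adjusted p = 0.0254 by permutation). The cause was not tested.

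The 156 genes with separate clusters became 102 at a distance of at least 1 log2 and 83 in the genes at or above a median level of 5.73, both subsets by construction, 66 without the 4 mice, 38 of them shared, and 22 without the 15 mice, 12 of them shared. Within stretches 129 genes passed, 70 of them shared, and with centred arrays 143, 109 of them shared, so calls changed more than their number; the cause was not tested. Losing mice lowers these counts in part by construction, since each cluster must hold 5. The 1031 genes related to the animal number became 1707 with blood and immune scores as covariates and 0 with the stretches as a block, where little of the number's variation is left; other alternatives gave from 780 to 1536. Signal over background was not analysed here.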

Other observations

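Some tests here were chosen after the data were seen: the blood and immune covariates on the animal number, the lists of pancreatic acinar, adipocyte, epithelial and erythroid precursor genes, the tests without the mice that stand apart on the drift and on clusters with fewer than 15 mice in one, the random sets of mice, and the test of genes near the clustered genes, which was added when the test between clustered genes proved empty.

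Erythropoiesis and proliferation went together in animal 64. All 11 erythroid precursor genes, such as Gata1, a master regulator of red cell formation, were highest there, and animal 257 was second in each. Hemgn was 9.61 in animal 64 against a median of 3.28, Ermap was 10.43 against 3.11 and Kel was 8.55 against 2.59. Of these genes 2 lay at or above the median level of all genes.

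Transcripts of other organs appeared in single livers. Ctrb1 was 12.30 in animal 96, 10.67 in animal 149 and 9.80 in animal 170, against a median of 4.34. Pancreas tissue taken with the liver is a candidate explanation: of 12 measured acinar genes not looked at before, none at or above the median level of liver genes, 83.3% had these animals as their 3 highest, with Cpb1 at 11.74 and Clps at 10.22 in animal 96, whose cholangiocyte score of 4.07 was also the highest. In animal 161, Csn1s2a, Csn3 and Lalba were 10.51, 11.07 and 9.09 against medians from 2.46 to 2.62, and mammary epithelial or tumour cells are a candidate source, since 69.2% of 13 epithelial genes, 2 of the 13 at or above the median level of liver genes, were highest there, although its cholangiocyte score of 2.99 was the second highest, its neutrophil score of 2.58 was the highest, and the milk gene Wap was not raised in any liver (highest 4.06, in animal 24). Mammary fat carried over was argued against, as animal 161 was at percentile 0 of the 6 adipocyte genes, with Adipoq at 2.63 against a median of 2.70. Of these genes 2, Plin4 and Pparg, lay at or above the median level of liver genes, so that rank rests in part on values near the floor. None of the 6 was raised in animal 161, and Pparg was 5.06 there against a median of 6.01. Tumour spread and carried-over epithelium stay open and were not tested.

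The drift with the animal number was not explained by chance order, which reached 6 genes at most over 100 random orders against 1031 (1 of 101 orders, the real one, gave as many). With the blood and immune scores as covariates 1707 genes passed, 874 of them among the 1031, which met the bound set against blood and immune content. Single mice dominate those scores. The erythroid score was 5.72 in animal 64 against an upper quartile of −0.04, and the T cell score 5.31 in animal 87 against 0.11. The fit therefore cannot exclude a graded difference in blood or immune content along the numbers. The mice that stand apart were argued against, since 1457 genes passed without them, 909 of them shared. A step between processing batches may contribute and stays open: 44.03% of the 1031 genes (454) had a single step larger than in 95% of simulated linear trends, below the share set beforehand for a step, and 26.0% had their step within 2 mice of animal 84. The numbers could also follow age, litter or collection, which the labels do not give, so none of these was tested.

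In 156 of 11090 genes values met the rule for 2 separate clusters. In data simulated from 1 normal per gene, with the mean and SD of the gene, 1 gene did. Such data hold no skew and no outlying mice, so this comparison does not tell clusters from a few outlying mice. Serpina1d had 20 mice at a mean of 5.67 and 30 at 11.80, Gm3893 had 25 at 3.26 and 25 at 5.78, B4galnt1 had 19 at 3.62 and 31 at 6.17, and 2610507I01Rik had 21 at 3.23 and 29 at 5.49. Gm7969, Snord99, Olfr1034 and Scarna6 also had at least 15 mice in each cluster.

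In 148 genes the smaller cluster held fewer than 15 mice, and the mice that stand apart may account for many of these: 20.3% kept their call without them, 30 genes against at least 50 in 100 random removals of 4 mice, and 89 genes had 3 or 4 of them in the smaller cluster, whereas Rrp1 kept its call with 7 mice in the smaller cluster, 0 of them standing apart, and the cause for such genes was not tested. In 8 genes each cluster held at least 15 mice, and 100% kept their call. That outcome was close to fixed in advance, since 4 mice cannot make up a cluster of 15. Random removals of 4 mice also kept at least 7 of the 8. Alleles that segregate in the backcross are a hypothesis. The mean r squared of these 8 genes with the 20 genes on either side was 0.0390, above the highest of 100 random placements, 0.0341. It came mainly from 2610507I01Rik (0.0604 with neighbours against 0.0216 with all genes), Gm7969 (0.0583 against 0.0244) and Gm3893 (0.0427 against 0.0218). The difference was smaller for Serpina1d (0.0238 against 0.0181), Snord99 (0.0249 against 0.0185) and Olfr1034 (0.0373 against 0.0346). B4galnt1 and Scarna6 were no closer to their neighbours than to other genes (0.0153 against 0.0267 and 0.0495 against 0.0557). The highest r squared of Gm3893 with a neighbour was 0.495. Neighbouring genes covaried slightly more in general, as given above, and genes without clusters were not compared at their own places. The comparison therefore does not tell alleles of the clustered genes from that general excess. The test between clustered genes of the same chromosome met the bound written beforehand against linked alleles, 0.132 within the range of the shuffles, but that bound was set aside after the value was seen, since only 1 pair shares a chromosome and shuffles can draw the same pair. A strain variant under a probe was not tested and stays open.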
